A study of Mus musculus with 6 samples.

How the data were processed

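Total RNA from microdissected whole lungs of mouse embryos at E16.5 (embryonic day) was measured on single-channel Affymetrix mouse expression arrays, with 1 array per sample. The labels give 3 Hopx-null and 3 wild-type lungs, described as biological replicates, on a mixed strain background. Per the labels' protocols, RNA was extracted with Trizol, reverse transcribed from a poly(T) primer and amplified as biotin-labelled cRNA, so the arrays favour sequence near the 3' ends of transcripts. RMA (robust multi-array averaging, which corrects background, equalises the arrays' distributions and summarises the probes of a probe set) and Partek 6.6 are named, per the submitters' processing notes, with no role or order given. The deposited values were read as log2 expression values. No header states the base of the logarithm, and log2 was inferred from the range of the values and from the use of RMA. Equalising the distributions removes any difference in total signal between arrays, so a shift of most transcripts in 1 direction would not be visible in these values. The background option and any filter applied by the authors are not given in the sources used here.

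The table held 45101 probe sets, of which 64 hybridisation and RNA controls were left out and 45037 were tested without a filter on dim probe sets. The platform annotation named 1 gene for 34945 probe sets, several genes for 932 and none for 9160, which are unnamed here. No gene was named from a probe set with several. For gene lists, each of 18194 genes was represented by the probe set with the highest mean over the 6 samples. Symbols were compared through gene identifiers with a RefSeq gene table of assembly GRCm38.p6, and 0 of them differed. The same table gave the order of neighbouring genes for 18032 genes, and none of its coordinates are reported. No 2 arrays shared more than 0.313% of identical values.

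Hopx-null and wild-type lungs were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options), and p-values were adjusted by the Benjamini-Hochberg method over all probe sets with a threshold of 0.05. Standard errors and 95% intervals come from the same fit. The 35 gene lists, with 654 entries of which 604 were measured, covered lung cell types, tissues that dissection could carry along, signalling pathways, maturation, stress and sex-linked genes. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 35 lists. The number of arrays limits the precision, and an exact two-sided permutation test of 3 against 3 samples cannot give a p below 0.1.

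The named genes followed a rule: Hopx first, then the genes with the largest changes in each direction among those that passed the threshold without overlap between groups, filled up where few passed to 8 per direction. The fill took the smallest unadjusted p among genes with no overlap between groups and a mean above the median of all probe sets. No gene other than Hopx passed, so all 16 came from the fill. Uncharacterised genes and small RNAs were skipped, 2 names in all. For each list described, the members that passed over the list alone were to be named or, where there were none, the 3 with the largest change, and Sftpc, Sftpb, Ager, Aqp5 and Pdpn were named in every case. Grouping, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were repeated normalization, filters on dim probe sets, other variance models, array weights, the replicate number as a block, other thresholds and each sample left out in turn. The sex-linked and cartilage covariates and the other Hopx probe set were added after seeing the data. So were the relations of the cartilage score to airway scores and most tests given under other observations.

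The procedures were tested on simulated data in 3 against 3 samples, with 45037 probe sets for limma, 18194 genes for camera and 18031 genes for the scan of neighbouring genes. Over 20 simulated data sets, limma recovered 6.7% of changes of 0.5 on the log2 scale, 59.1% of changes of 1, 88.5% of changes of 2 and 96.2% of changes of 3. Of 2625 limma calls in these data, 120 were false. Many changed probe sets were planted in each data set, which loosens the Benjamini-Hochberg cutoff. Recovery would be lower where few probe sets change, as in the real comparison, where 2 probe sets passed. A list shifted by 0.5 was recovered by camera in 20 of 20 data sets, and 2 of 641 unshifted lists were called. Simulated genes were independent, so this does not show how camera behaves on correlated genes. Camera with an estimated correlation was not run on simulated data, so its power is not known. In the real data it gave every list the same adjusted p, 0.985 (Benjamini-Hochberg), which says little about any single list. The scan for neighbouring genes found 20 of 20 planted clusters and called 1 of 20 data sets without one. Each planted cluster held 12 genes among 50 neighbours, against a 95th percentile of shuffles of 6, so finding it was nearly assured. Clusters of 8 or 7 genes, the sizes described below, were not simulated. Figures were drawn with matplotlib 3.10.9.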

Results

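Gene expression was measured in lungs of embryos lacking Hopx and of wild-type embryos at E16.5, with 3 samples per genotype. Hopx encodes a small atypical homeodomain protein that marks type I alveolar cells, the flat gas-exchange cells of the lung. Correlations between arrays ranged from 0.991 to 0.995 within a genotype and from 0.989 to 0.995 between genotypes. The median log2 change over all probe sets was 0.01. Hopx-null replicate 3 had the largest 3' bias in the control probe sets. Its log2 differences between 3' and 5' probe sets were 1.51 for actin and 1.72 for Gapdh, against 1.15 to 1.25 and 1.42 to 1.60 in the other samples.

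The comparison asks how loss of Hopx alters the transcriptome of the fetal lung. Hopx itself was lower in Hopx-null lungs at both of its probe sets, and these were the only 2 of 45037 probe sets that passed the threshold. At the probe set with the suffix s_at the log2 value fell from 10.65 ± 0.28 (SD, n = 3) in wild-type to 4.71 ± 0.21 (SD, n = 3) in Hopx-null lungs. The latter level is near the lower quartile of the arrays (4.24 to 4.30), where signal is close to background, so no exact fold is given. At the probe set with the suffix a_at it fell from 12.40 ± 0.13 (SD, n = 3) to 10.49 ± 0.15 (SD, n = 3), 3.76-fold lower. Hopx-null lungs thus still read above the upper quartile of the arrays (9.02 to 9.05) at the a_at probe set. The measured log2 difference at the s_at probe set, a lower limit in size because of that background, was -5.94 (SE 0.17, limma eBayes with Benjamini-Hochberg, adjusted p = 0.000375), and the change at the a_at probe set was -1.91 (SE 0.11, limma eBayes with Benjamini-Hochberg, adjusted p = 0.0228). All 3 Hopx-null samples lay below all 3 wild-type samples at both probe sets. The deleted part of the gene and the place of each probe set in the transcript are not given in the sources used here, so the different size of the changes was not examined further. The change at the a_at probe set no longer passed in limma (eBayes, Benjamini-Hochberg) without Hopx-null replicate 2 (adjusted p = 0.226), Hopx-null replicate 3 (adjusted p = 0.413), wild-type replicate 2 (adjusted p = 0.231) or wild-type replicate 3 (adjusted p = 0.103), whereas the s_at probe set passed whichever sample was left out.

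**Figure D1:**
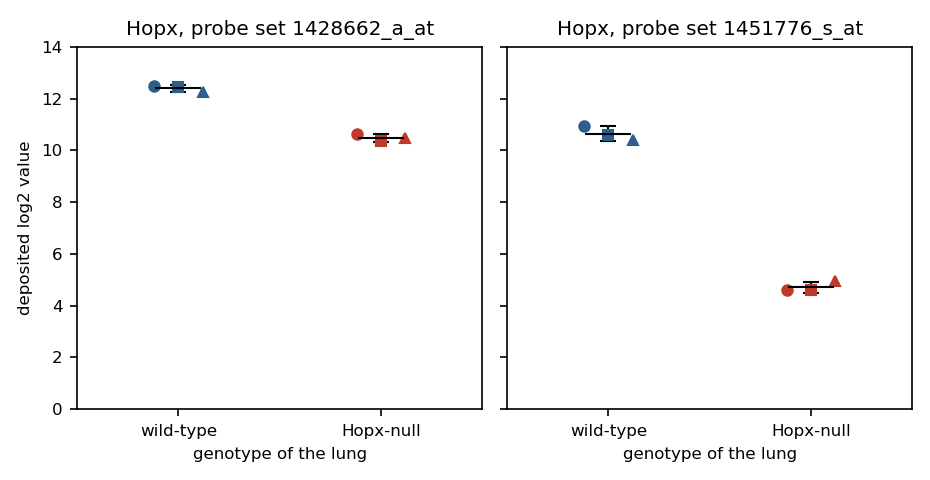
Deposited log2 values of both Hopx probe sets in each lung sample, by genotype, with circles, squares and triangles for replicates 1, 2 and 3 and horizontal marks with bars for the mean and SD of 3 samples. Hopx-null samples averaged 10.49 at the a_at probe set (left) and 4.71 at the s_at probe set (right), against 12.40 and 10.65 in wild-type samples.

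No other probe set was called by limma (eBayes, Benjamini-Hochberg), and the smallest adjusted p outside Hopx was 0.878. At an unadjusted p under 0.05 there were 2149 probe sets, 1248 higher and 901 lower in Hopx-null lungs, against 2252 from chance alone. The groups did not overlap at 10.1% of probe sets, and chance gives 10% for 3 against 3. Without Hopx-null replicate 1 the counts became 6 higher and 6 lower, including 3 probe sets of the histocompatibility gene H2-D1 that differ among the Hopx-null samples. Without wild-type replicate 1 they became 5 higher and 18 lower, with probe sets of the sex-linked genes Xist, Eif2s3y, Uty and Kdm5d among them, since both wild-type samples left carry Y-linked signal.

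Among the genes taken by the naming rule, none passed the test. Those with higher values in Hopx-null lungs were Paqr7, a membrane progestin receptor, with a log2 difference of 1.09 (SE 0.20), Naip5, an inflammasome sensor, with 0.75 (SE 0.13), Scn3a, a sodium channel subunit, with 0.72 (SE 0.13), and Hlx, a homeobox factor, with 0.70 (SE 0.12). Chodl differed by 0.57, the tyrosine-breakdown enzyme Fah by 0.56, the matrix metalloproteinase Mmp2 by 0.54 and the chromatin assembly factor Chaf1b by 0.48. A second probe set of Paqr7 and of Chaf1b differed in the other direction, that of Scn3a differed by 0.08 and that of Mmp2 by 0.54. Those with lower values were Pnliprp1 with a log2 difference of -1.14 (SE 0.30), the peptide transporter Slc15a2 with -0.57 (SE 0.09), Oas1e with -0.56 (SE 0.13) and the metalloproteinase Mmp19 with -0.45 (SE 0.11). Gng4 differed by -0.43, the hedgehog ligand Dhh by -0.37, Zfp592 by -0.36 and Stx19 by -0.35. Further probe sets of these genes gave -0.09 and -0.16 for Slc15a2, -0.12 and -0.05 for Zfp592, -0.33 and -0.13 for Gng4, -0.31 for Mmp19 and -0.25 for Dhh. Each of these 16 genes had an adjusted p of 0.878 in limma (eBayes, Benjamini-Hochberg).

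Markers of type I alveolar cells, listed without Hopx, did not pass as a group. Their median log2 difference was 0.12, with 17 of 21 measured genes higher and 4 lower in Hopx-null lungs (limma camera, Benjamini-Hochberg, adjusted p = 0.291). None of them passed limma over all probe sets or adjusted over the list alone. The receptor gene Ager differed by 0.14 (95% interval -0.10 to 0.38), the water channel Aqp5 by 0.18 (95% interval -0.19 to 0.55) and podoplanin, Pdpn, by 0.21 (95% interval -0.39 to 0.80). The largest differences in the list were 0.41 for Akap5, 0.35 for Spock2 and 0.32 for Sema3a. The list mean of wild-type replicate 3 was 11.44, and the other samples lay between 11.88 and 11.94. Without wild-type replicate 3 the list median was -0.03. Without wild-type replicate 1, where both wild-type samples left carry Y-linked signal, the list was 1 of 10 that passed, at 0.14 (limma camera, Benjamini-Hochberg, adjusted p = 0.0164). Over all 6 samples, limma camera with an estimated correlation gave a Benjamini-Hochberg adjusted p of 0.985. Every list had that value, which says little about this one.

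Markers of type II alveolar cells, the surfactant-producing cells, had a median log2 difference of 0.04, with 14 of 22 genes higher and 8 lower (limma camera, Benjamini-Hochberg, adjusted p = 0.493), and no member passed over all probe sets or adjusted over the list alone. The surfactant protein genes Sftpc and Sftpb differed by 0.00 (95% interval -0.19 to 0.20) and 0.11 (95% interval -0.08 to 0.30). Chil1 differed by -0.78, Il33 by 0.26 and Sftpa1 by 0.19. This median was -0.01 without Hopx-null replicate 2 and -0.0014 without wild-type replicate 3. Genes of surfactant lipid synthesis had a median of 0.01, with 11 of 18 higher, and Lpin1 at -0.69, Elovl6 at 0.31 and Abca3 at 0.19 differed most. Leaving out each sample in turn, that median ranged from 0.00019 to 0.028. Distal tip progenitor genes and lung epithelial regulators were evenly divided, 10 higher and 10 lower, with Mycn at 0.38, Bmp4 at 0.34 and Foxa2 at -0.28.

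**Figure D2:**
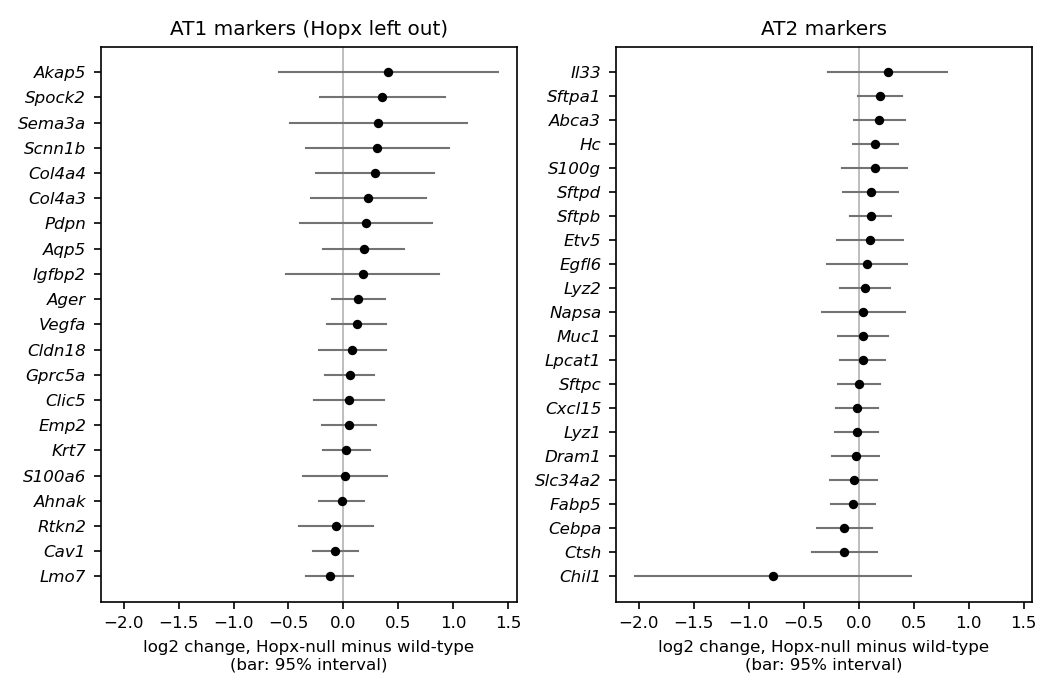
Log2 change, Hopx-null minus wild-type, for each measured marker of type I (left) and type II (right) alveolar cells, with points for the estimate and bars for its 95% interval from limma over 3 samples per genotype. Of the type I markers 17 lie above 0 and 4 below, and of the type II markers 14 lie above and 8 below.

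Of the 35 gene lists, 2 passed camera, both lower in Hopx-null lungs. The estimated correlation between genes was 0.546 in the cartilage list and 0.627 in the interferon list, against the preset of 0.01. Camera p-values at the preset can therefore be far too small for both lists. At this preset, at least 2 lists passed in 9 of the 10 splits of the samples into 3 and 3, the real one included. Cartilage markers had a median log2 change of -0.96, with 13 of 15 genes lower (limma camera, Benjamini-Hochberg, adjusted p = 0.000637), and camera gave adjusted p = 0.985 with an estimated correlation, as for every list. The proteoglycan Acan differed by -1.71 (95% interval -3.62 to 0.20) and the collagens Col9a3 and Col9a1 by -1.66 (95% interval -4.06 to 0.74) and -1.56 (95% interval -5.14 to 2.02), and none of these genes passed alone. The list means were 5.77, 5.28 and 6.07 in Hopx-null replicates 1 to 3, and 5.23, 7.14 and 7.32 in wild-type replicates 1 to 3, which an exact two-sided permutation test did not separate (p = 0.4). The list no longer passed camera without wild-type replicate 2 (limma camera, Benjamini-Hochberg, median -0.56, adjusted p = 0.109) or wild-type replicate 3 (median -0.54, adjusted p = 0.085). Without wild-type replicate 1 the median was -1.81 (limma camera, Benjamini-Hochberg, adjusted p = 2.6e-17), but there both wild-type samples left carry Y-linked signal and no Hopx-null sample does. With Y-linked expression as a covariate, chosen after seeing the data, the median was 0.27. Only wild-type replicates 2 and 3 carry Y-linked signal, so that fit in effect sets the Hopx-null samples against wild-type replicate 1 alone. Among 4 relations computed over the 6 samples, deviations from the genotype mean in the cartilage and secretory airway scores correlated (Pearson r = 0.970, exact permutation p = 0.00833, Benjamini-Hochberg adjusted 0.0333, Spearman rho = 0.886, exact permutation p = 0.0333), with r = 0.666 without the 2 samples farthest from the median. This relation was chosen after the cartilage result had been seen. Its permutation p-values shuffle all 6 deviations freely, although deviations cancel within a genotype. They can therefore be too small, and the relation is not taken as passing a test. Cartilage scores spread most among wild-type samples (SD 1.16 against 0.40). There replicate 1, without Y-linked signal, was lowest in both scores, so the relation does not separate airway content from sex.

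Interferon-stimulated genes had a median log2 change of -0.71, with 14 of 15 genes lower (limma camera, Benjamini-Hochberg, adjusted p = 0.000559), and camera gave adjusted p = 0.985 with an estimated correlation, as for every list. The antiviral gene Ifit1 differed by -1.53 (SE 0.68), Oasl2 by -0.95 (SE 0.70) and the transcription factor Irf7 by -0.90 (SE 0.45), and none of these genes passed alone. The list means were 8.40, 8.28 and 8.04 in Hopx-null replicates 1 to 3 and 8.92, 8.04 and 9.48 in wild-type replicates 1 to 3 (exact two-sided permutation p = 0.3). The list no longer passed without wild-type replicate 3 (limma camera, Benjamini-Hochberg, median -0.20, adjusted p = 0.148) or with dim list members left out (median -0.26, adjusted p = 0.0991). It still passed with only probe sets above the median (limma camera, Benjamini-Hochberg, median -0.73, adjusted p = 0.000279). No list passed fry, where the smallest adjusted p was 0.776 for a shift in 1 direction and 0.744 for changes in either direction (limma, Benjamini-Hochberg).

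Sex-linked genes differed between samples of the same genotype. The Y-linked gene Eif2s3y read 11.7 and 11.6 in wild-type replicates 2 and 3 and between 2.88 and 3.13 in the other 4 samples. Xist, expressed from the inactive X chromosome, read 6.43 and 5.84 in wild-type replicates 2 and 3 and between 12.2 and 12.7 in the others. Signal from Y-linked genes was thus present in 2 of 3 wild-type and 0 of 3 Hopx-null samples, and the 2 samples that carry it also had the highest cartilage list means. The list of Y-linked and X-inactivation genes had a median of -1.71 (limma camera, Benjamini-Hochberg, adjusted p = 0.191), with Eif2s3y at -5.85, Xist at 4.44 and Kdm5d at -4.38. It passed without wild-type replicate 1, where both wild-type samples left carry Y-linked signal (limma camera, Benjamini-Hochberg, median -2.45, adjusted p = 7.2e-06). Eif2s3y and Kdm5d read below the lower quartile of the arrays in all Hopx-null samples, so their differences are lower limits in size.

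With all samples the other lists did not pass, and their medians lay between -0.18 for neural and Schwann cell markers and 0.16 for cardiac muscle markers. The adjusted p of 0.985 from limma camera with an estimated correlation was that of every list and says little about any single one. The neural list, with Sox10 at -0.65, Ret at -0.59 and Nefl at -0.56, passed without Hopx-null replicate 3 (limma camera, Benjamini-Hochberg, median -0.28, adjusted p = 0.0299) and without wild-type replicate 1 (median -0.39, adjusted p = 0.0025). In the other direction, its median was -0.06 without Hopx-null replicate 2 and reached 0.014 with another sample left out. The multiciliated, neuroendocrine, squamous and late-gestation lists also passed without wild-type replicate 1 (limma camera, Benjamini-Hochberg, adjusted p = 0.00102, 0.0473, 0.0473 and 0.0299), and each of these lists had adjusted p = 0.985 with an estimated correlation over all samples. The cardiac list, with Myh7 at 0.73, Nppa at -0.67 and Myl2 at 0.63, passed without wild-type replicate 3 at a median of 0.33 (limma camera, Benjamini-Hochberg, adjusted p = 5.6e-05), and its median was -0.01 without wild-type replicate 1. Over all 6 samples the cardiac list had adjusted p = 0.291, and 0.985 with an estimated correlation (limma camera, Benjamini-Hochberg). Cell cycle genes, with Mcm5 at 0.67, Ccnb2 at -0.51 and Mcm2 at 0.46, had a median of -0.06 (limma camera, Benjamini-Hochberg, adjusted p = 0.904, and 0.985 with an estimated correlation), which without wild-type replicate 3 was 0.17 and passed (adjusted p = 0.00733). Nuclear-encoded oxidative phosphorylation genes were higher in 18 of 23 members with a median of 0.05 (limma camera, Benjamini-Hochberg, adjusted p = 0.228, 0.0397 with trend and robust options and 0.985 with an estimated correlation), with Ndufa1 at 0.19, Cox6c at 0.17 and Ndufb9 at 0.14. Leaving out 1 sample, the median of this list ranged from 0.033 without Hopx-null replicate 3 to 0.070 without wild-type replicate 1. Secretory airway cell markers were lower in 10 of 14 members with a median of -0.04 (limma camera, Benjamini-Hochberg, adjusted p = 0.291), with Sox2 at -0.77, Scgb3a1 at -0.72 and Pon1 at -0.38. Their median was -0.0045 without wild-type replicate 2 and -0.13 without wild-type replicate 1, where the list passed (limma camera, Benjamini-Hochberg, adjusted p = 0.0164, against 0.985 with an estimated correlation over all samples). Wnt pathway targets had a median of 0.05 and TGF-beta response genes of 0.06, with Dkk2 at 0.46, Wif1 at 0.45 and Wnt2 at 0.43 in the Wnt list and Itgb6 at 0.66, Tgfb3 at 0.39 and Bhlhe40 at 0.36 in the TGF-beta list. Leaving out 1 sample, these medians reached 0.15 for the Wnt list without Hopx-null replicate 1 and 0.013 for the TGF-beta list without wild-type replicate 3, and neither list passed in any such setting. Targets of serum response factor, SRF, a transcription factor that Hopx can inhibit, had a median of 0.03, with Egr2 at 0.64, Ankrd1 at -0.41 and Fos at -0.41, and the median ranged from -0.03 without wild-type replicate 1 to 0.08 without wild-type replicate 3. The median and the mean had opposite signs for the lymphatic, erythroid, smooth muscle and immediate-early lists, and camera's direction was opposite to the median for the lymphatic and distal tip lists.

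**Figure D3:**
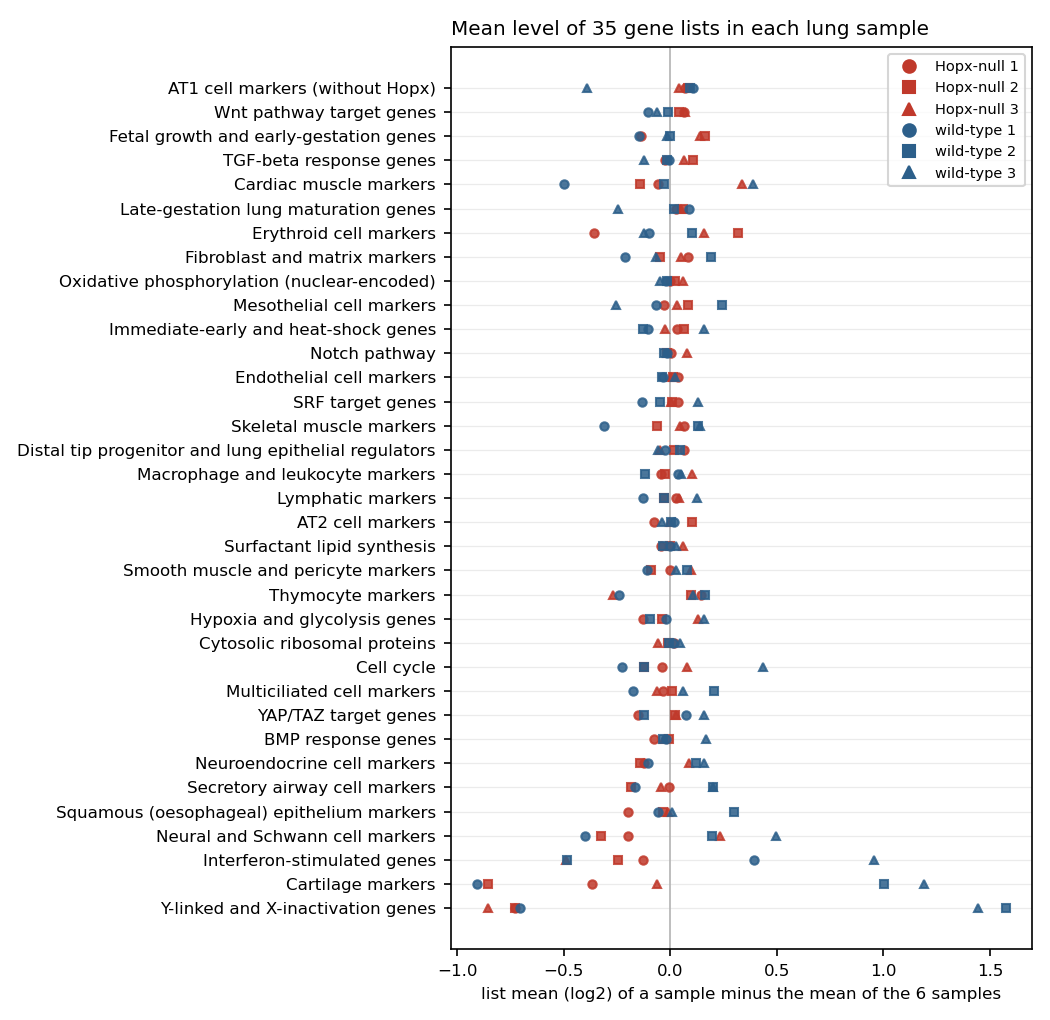
Mean log2 level of each of the 35 gene lists in each lung sample, minus the mean of the 6 samples, with color for genotype and circles, squares and triangles for replicates 1, 2 and 3. In the cartilage list, wild-type replicates 2 and 3 (7.14 and 7.32 before centring) lie to the right of the other 4 samples, and in the interferon list wild-type replicates 1 and 3 (8.92 and 9.48) do.

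Genes near Hopx were examined because a targeted allele can carry flanking DNA of the donor strain. Of 200 measured genes within 20 Mb on the same chromosome (order from assembly GRCm38.p6), 0 passed limma's threshold, as did 0 of the 17831 genes elsewhere. At an unadjusted p under 0.01 there were 2 near Hopx, Spink2 and Cox7b2, and 119 elsewhere, 1% against 0.667% (Fisher's exact test, two-sided, p = 0.389). Within 10 Mb there were 2 of 82 genes, 2.44% against 0.663% elsewhere (Fisher's exact test, two-sided, p = 0.105). Spink2, a protease inhibitor gene and the third nearest measured gene to Hopx, read 5.39 ± 0.06 (SD, n = 3) in Hopx-null and 6.66 ± 0.42 (SD, n = 3) in wild-type lungs, a log2 difference of -1.28 that did not pass limma (eBayes, Benjamini-Hochberg, adjusted p = 0.878). Both genes were singled out after their values were seen.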

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

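The covariates for Y-linked expression and the cartilage score and the other Hopx probe set were chosen after seeing the data. Only wild-type replicates 2 and 3 carried Y-linked signal. Every difference given with the Y-linked covariate therefore rests on wild-type replicate 1 against the Hopx-null samples. Unless stated, the cause of a change was not tested. The 16 named genes kept their direction and stayed short of the threshold, and Hopx stayed lower at both probe sets, under repeated normalization, the filter on dim probe sets, trend and robust options, array weights, the replicate block, both covariates and each sample left out. With 1 probe set per gene, Hopx passed at its a_at probe set (-1.91, limma, Benjamini-Hochberg, adjusted p = 0.0211), and the named genes were not computed singly. The count of lower probe sets became 1 with 1 probe set per gene (fewer tested), with the replicate block and with either covariate, and ranged from 1 to 18 over the samples left out, with 0 to 6 higher. The Hopx change at the a_at probe set was -1.91 with the replicate block (limma, Benjamini-Hochberg, adjusted p = 0.299), -2.02 with the Y-linked covariate (adjusted p = 0.393) and -1.96 with the cartilage covariate (adjusted p = 0.256), none past the threshold; leaving out samples it ranged from -1.99 to -1.84 (adjusted p 0.0172 to 0.413), and the difference at the s_at probe set, a lower limit in size, from -6.06 to -5.78 (adjusted p 0.00014 to 0.0109). Replicate numbers did not pair the samples (correlations of deviations -0.0958, -0.121 and 0.183), and under the block only the s_at probe set of Hopx passed (adjusted p = 0.0327). Near Hopx, 2 genes counted at an unadjusted p under 0.01 in place of 0.

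The number of lists past camera was 1 with only probe sets above the median, 3 with trend and robust options, 0 with an estimated correlation, 0 with dim list members left out, 5 with the Y-linked covariate and 4 with the cartilage covariate, and ranged from 1 to 10 over the samples left out. Under both filters on dim genes, the cartilage, neural, neuroendocrine, skeletal muscle, squamous, thymocyte and sex-linked lists kept under 5 genes and were not tested, nor was the erythroid list with dim members left out, so the cartilage list did not fail there. Oxidative phosphorylation passed with trend and robust options (0.0534, limma camera, Benjamini-Hochberg, adjusted p = 0.0397). With the Y-linked covariate the cardiac (0.58, adjusted p = 2.8e-07), skeletal muscle (0.33, adjusted p = 0.000109) and cell cycle lists (adjusted p = 0.0152) passed as well, and with the cartilage covariate the cardiac (0.44, adjusted p = 8.2e-08), skeletal muscle (0.22, adjusted p = 0.00737) and sex-linked lists (-0.90, adjusted p = 0.0313) did. The interferon list stayed at -0.71 and the cartilage list at -0.96 with an estimated correlation (limma camera, Benjamini-Hochberg, adjusted p = 0.985 for both, as for the other lists), and the interferon list was -0.26 with dim members left out (adjusted p = 0.0991). Median list shifts turned sign as follows. After repeated quantile normalization this was distal tip -0.00936. With equal array medians these were surfactant lipid synthesis -0.00531, distal tip -0.00805, fibroblast and matrix -0.00782. With only probe sets above the median this was distal tip -0.0157. With array weights these were lymphatic 0.0027, fibroblast and matrix -0.00576. With the mean over a gene's probe sets these were distal tip -0.0183, lymphatic 0.0742, smooth muscle and pericyte 0.0224, BMP response genes 0.0269. With dim list members left out these were distal tip -0.0263, mesothelial -0.0279, early-gestation -0.0404. With the Y-linked covariate these were type I marker -0.057, cartilage 0.27 (higher and past the threshold, limma camera, Benjamini-Hochberg, adjusted p = 0.0493), secretory airway 0.0319, multiciliated 0.076, neuroendocrine 0.00577, lymphatic 0.17, smooth muscle and pericyte 0.047, leukocyte -0.0459, thymocyte 0.12, neural and Schwann 0.31, cell cycle 0.19, immediate-early and heat-shock genes 0.0205, hypoxia and glycolysis genes 0.0144, late-gestation -0.0176. With the cartilage covariate these were type II marker -0.00343, distal tip -0.000249, secretory airway 0.0185, multiciliated 0.00964, lymphatic 0.0722, smooth muscle and pericyte 0.0127, thymocyte 0.035, squamous 0.00102, neural and Schwann 0.19, cell cycle 0.12, hypoxia and glycolysis genes 0.0219, late-gestation -0.00184. Leaving out each sample, the medians ranged as follows: secretory airway -0.13 to -0.0045, Wnt 0.0666 to 0.15, TGF-beta 0.0134 to 0.0965, type I marker -0.0323 to 0.17, type II marker -0.0136 to 0.0641, interferon -0.99 to -0.20, cartilage -1.81 to -0.54, distal tip -0.0179 to 0.0581, multiciliated -0.18 to 0.00738, lymphatic -0.11 to 0.0633, fibroblast and matrix -0.0102 to 0.10, smooth muscle and pericyte -0.0173 to 0.0516, mesothelial -0.0821 to 0.28, leukocyte -0.0113 to 0.11, cardiac muscle -0.0133 to 0.33, skeletal muscle -0.0323 to 0.12, thymocyte -0.21 to 0.0746, neural and Schwann -0.39 to 0.014, cell cycle -0.23 to 0.17, SRF target genes -0.0282 to 0.0804, BMP response genes -0.13 to 0.00678, immediate-early and heat-shock genes -0.0692 to 0.0031, hypoxia and glycolysis genes -0.0602 to 0.0598, late-gestation -0.0246 to 0.15. Sex and genotype are partly confounded, and signal over background limits the dim lists.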

Other observations

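Apart from the count of lists in other splits of the samples and the relation of interferon to leukocyte scores, the tests in this part were chosen after the results they concern had been seen, and for 4 of them (sex for cartilage, leukocytes for interferon, chance placement and haplotypes for the gene cluster) a stricter condition was added once the value was known: each had met a bound against the explanation, chance placement only in a revised scan, and each is left open here. A few related genes were picked after their values were seen; none passed limma over all probe sets or over its list alone, no group of them was tested, and most go against their own list. The complement genes C1qc, C1qa and C1qb, made by macrophages, differed by -0.38, -0.30 and -0.29 in Hopx-null lungs, while 12 of 17 leukocyte markers were higher. The embryonic globins Hbb-y and Hba-x differed by 1.17 and 0.70, with standard errors of 0.79 and 0.64, while 8 of 12 erythroid markers were lower. Nr4a1 differed by 0.93, while 13 of 21 immediate-early and heat-shock genes were lower. The replication genes Mcm5 and Mcm2 differed by 0.67 and 0.46, while 16 of 24 cell cycle genes were lower. The BMP target Id1 differed by -0.67 in a list with 8 genes higher and 8 lower.

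Probe sets of the class I histocompatibility gene H2-D1 differed between samples of 1 genotype. At 1 of them the log2 values were 11.08 and 11.49 in Hopx-null replicates 2 and 3, 4.88 in Hopx-null replicate 1 and between 4.58 and 4.98 in the wild-type samples. Of the 9 probe sets of H2-D1, 3 divided the samples in this way, the other two reading 5.06 and 5.23 in Hopx-null replicate 1 and at least 9.76 and 10.68 in Hopx-null replicates 2 and 3, while another probe set of H2-D1 ranged from 10.48 to 11.25 over the 6 samples.

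The cartilage list passed as lower in Hopx-null lungs at camera's preset correlation only. With an estimated correlation its adjusted p was 0.985, as for every list (limma camera, Benjamini-Hochberg). The exact permutation p was 0.4, and no member passed. Wild-type replicate 1 (5.23) lay below all 3 Hopx-null samples. The spread within wild-type samples (2.10 between the lowest and highest list mean) exceeded the difference between genotypes (0.86). Unequal amounts of trachea or large airway in the dissected lungs may account for the cartilage difference. Over the 6 samples, deviations from the genotype mean in the cartilage score and in 3 airway scores had a mean correlation of 0.740, above the 0.5 set for this explanation. Among wild-type samples, replicate 1, without Y-linked signal, was lowest in the cartilage score and all 3 airway scores. The correlation therefore does not separate airway content from sex. Permutation p-values of correlated deviations shuffle all 6 deviations freely, although deviations cancel within a genotype. They can therefore be too small, and no relation is taken as passing a test. Of the 4 relations computed in the family, that with secretory airway markers was the strongest. It had Pearson r = 0.970 (exact permutation p = 0.00833, Benjamini-Hochberg adjusted 0.0333) and Spearman rho = 0.886 (exact permutation p = 0.0333). Without the 2 farthest samples its r was 0.666. For multiciliated and squamous markers r was 0.771 and 0.478 (exact permutation p = 0.0944 and 0.368), falling to 0.436 and 0.322 without the 2 farthest samples. Their rho was 0.486 and 0.543 (exact permutation p = 0.356 and 0.297). Sex of the embryos stays open: the range of the 4 samples without Y-linked signal was 0.513 of the difference between samples with and without it, just past the bound of 0.5 set against this explanation, but, in the condition added later, that ratio ran from 0.299 to 0.547 when 1 of the 4 was left out. The cartilage shift turned to 0.27 with Y-linked expression as a covariate. That fit sets the Hopx-null samples against wild-type replicate 1 alone, so the turn of sign does not decide the question. An effect of the genotype also stays open, since no Hopx-null sample carried Y-linked signal.

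The interferon list passed as lower in Hopx-null lungs at camera's preset correlation only. With an estimated correlation its adjusted p was 0.985, as for every list, and by fry it was 0.919 (limma camera and fry, Benjamini-Hochberg). The exact permutation p was 0.3, and no member passed. The list lost its camera call without wild-type replicate 3 (-0.20, adjusted p = 0.148) and with dim list members left out (-0.26, adjusted p = 0.0991). List means had a range of 1.44 among wild-type samples against a difference of 0.58 between genotypes. Sex of the embryos met the bound set against it. Wild-type replicate 1, without Y-linked signal, lay 0.521 above the highest Hopx-null sample, more than the range of 0.359 among Hopx-null samples. Wild-type replicate 2, with Y-linked signal, lay among the Hopx-null samples at 8.04, while wild-type replicate 3, also with it, was highest at 9.48. These values go against sex as the only source, but they rest on single wild-type samples, so a part played by sex stays open. More leukocytes in some wild-type lungs cannot be told apart from other explanations with 6 samples: the deviations of interferon and leukocyte scores correlated at r = 0.553 (exact permutation p = 0.265, Benjamini-Hochberg adjusted 0.354, Spearman rho = 0.257, exact permutation p = 0.658), r was -0.758 without the 2 farthest samples, and the leukocyte score was 0.02 higher in Hopx-null than in wild-type lungs, which met the bound against this explanation but only within the spread between samples. An effect of the genotype stays open as well.

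Top-ranked genes lay near one another on chromosome 11 in 1 of 2 scans. The scan first written, of genes with an unadjusted p under 0.01 among 25 neighbours, reached 3 genes at most, as many as in 0.706 of 10000 shuffles of the genes' places, and a revised scan, set after genes of chromosome 11 had been noticed in the ranked list, found 8 of the 300 top genes, ranked by the smallest p over a gene's probe sets, among 50 neighbours (Ccl9, Synrg, Acaca, Brip1os, Ints2, Rnft1, Tubd1 and Cltc; shuffle permutation p = 0.0039), and 7 in a stretch of chromosome 7 that holds Fah and Zfp592, also above the 95th percentile of the shuffles, 6. Chance placement therefore cannot be told apart from a real cluster, because the scan that found it was revised on these data and the first scan found none, although the second alone met the bound against chance. Strain haplotypes that differ between the groups may give such a cluster. Another split of the samples reached 13 genes, on chromosome 15, which met the bound set against this explanation. Haplotypes segregating in a mixed background could give clusters in other splits too, so that bound could not decide the question. Of the other 9 splits, 7 exceeded the 95th percentile of the shuffles. The shuffles treat neighbouring genes as independent and the strain origin of the stretch was not measured, so these clusters do not argue for haplotypes. An altered copy number of the stretch stays open as well, with 1 of the 8 genes, Ints2, lower and the others higher; for 6 of the 8 genes only 1 of 2 probe sets had an unadjusted p under 0.05, which excludes nothing.

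With 10 splits of the 6 samples into 3 and 3, the share of splits cannot fall under 0.05. At least 2 probe sets were called in 3 of the 10 splits, the real one with 2 included, and the highest other gave 4. At least 2 lists passed camera in 9 of the 10 splits, the real one with 2 included, and the highest other gave 12 (0 lists passed in the real split with an estimated correlation). At an unadjusted p under 0.01 the real split gave 340 probe sets and the other splits 91, 155, 159, 312, 344, 455, 519, 681 and 1098. The split with 1098, of Hopx-null replicate 1 with wild-type replicates 2 and 3, points to a structure of the samples, whose cause was not tested.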
